A study of Micropterus salmoides with 16 samples.

How the data were processed

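The study deposited 16 scans of single-colour (Cy3) arrays from 4 groups: liver and ovary of adult female largemouth bass, each with EE2 feed or control feed and 4 arrays per group. Per the labels, the EE2 feed held 70 ng EE2 per g and gave about 351 ng per day over 60 days, with feeding on 5 days of each week, and 2 tanks were used, 1 per treatment. The labels do not say that each array is from a separate fish, or whether liver and ovary came from the same fish, so p-values measure only the spread between these samples. The liver arrays were on 1 slide and the ovary arrays on another, with EE2 and control arrays in separate rows of each.

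Per the file headers, the scanner files hold spot intensity from Agilent Feature Extraction 10.1.1.1, where the processed signal is background-subtracted and detrended within each array and is not normalized between arrays. The deposited value table holds log2 values. Checked against the scanner files, each of its columns is the log2 of the processed signal minus the median of the array, so its median is 0, and its blank cells are as many as the outlier spots of the array. Outlier spots numbered 5 to 27 on liver arrays and 13 to 46 on ovary arrays, and 0 spots were saturated. Each array held 15744 spots, with 15208 probes of 15155 distinct sequences, 53 of which were on 2 probes.

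From the scanner files, the log2 of the processed signal was taken and the 75th percentile of each array subtracted, leaving outlier spots blank. A probe was tested in a tissue if it was well above background on at least 4 of its 8 arrays, by the detection column of the scanner files. Each tissue was fitted on its own with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over the probes tested and a threshold of adjusted p under 0.05. The difference in EE2 effect between tissues was an interaction term in 1 fit of all 16 arrays, over probes tested in both tissues. A fold against a group with 0 of 4 arrays well above background was computed as a bound against its background limit. Per array, that limit was the higher of the probe's own signal and the lowest signal of any probe well above background. Spots not well above background can lie above that limit, so the bound is no guarantee. It holds only under this processing. The overlap was tested with Fisher's exact test per direction.

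Before the data were examined, the comparisons, tests, 38 gene lists, rule for named genes and most alternatives were fixed. The gene lists and the naming rule could not be applied: 0 probes had a gene description, and of 29 source names that look like accessions 0 matched the reference table of assembly ASM1485139v1. In their place, a rule set after the data were examined names 2 liver probes that rose and 2 that fell, by the size of the fitted log2 change, among those that passed and whose EE2 and control arrays did not overlap. For UF_Msa_CF_124951 the fitted change rests on controls that were not above background. Only a bound on its rise is given, for this processing, and its rank among the rises is not settled. In ovary, among probes with a value on all 8 arrays, that with the smallest p in each direction is named as a value that did not pass, and the interaction reuses the liver probes. After the data were examined, 4 groups of probes defined by signal and detection were tested with camera (preset correlation 0.01), with an estimated correlation and with fry.

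Tested on simulated data with 200 changed probes, the fit recovered 13.4% of liver probes changed by 1 log2 unit, 83.6% of those changed by 2 and 95.5% of those changed by 3, with 3.03% false calls. In ovary it recovered 47.8%, 80.6% and 95.5%, with 8.02% false calls. For the interaction it recovered 14.9%, 67.2% and 89.4%, with 5.79% false calls. The simulated noise was drawn independently for each probe and array, so these shares may not hold where probes vary together across arrays.

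Alternatives were quantile normalization, median scaling, normexp background correction (offset 50) alone and with quantile normalization, no filter on dim probes, a filter on all arrays, eBayes with trend and robust, array weights and the deposited value table. Others were the replicate block, all 16 arrays in 1 fit, separate tissue fits with a z test, looser thresholds and each array left out in turn. The normexp offset is added to every signal, which by itself shrinks the log2 change of a dim probe. EE2 and control arrays of a tissue with the same replicate number lay in the same slide column, so the replicate block is also a block on each column. Slide columns as a block, and fits within outer or inner columns, were added after the data were examined. Spike-in spots, 10 kinds with 20 spots each, were left out of the tests and used only to compare arrays. Their mean, relative to the 75th percentile, used only kinds with every spot well above background on every array of the tissue. These were 8 of 10 kinds in liver and 6 of 10 in ovary.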

Results

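RNA abundance was measured in the liver and ovary of adult female largemouth bass fed ethinylestradiol (EE2), a synthetic oestrogen, or control feed for 60 days. Each of 16 single-colour arrays held 15208 probes of 60 nt, with 4 EE2 and 4 control arrays per tissue. The 75th percentile of signal ran from 306.3 to 522.1 on liver arrays and from 3800 to 8713 on ovary arrays. Between 56.6% and 72.7% of liver probes and between 77.1% and 87.8% of ovary probes were well above background, and the number of arrays limits the precision of every value. On at least 4 arrays of the tissue, 9740 probes were well above background in both tissues, 603 in liver alone, 3025 in ovary alone and 1840 in neither. The files pair no probe with a gene, so probes are given by identifier and sequence.

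The liver comparison addressed whether dietary EE2 altered hepatic transcript abundance, and 20 of 10343 probes passed limma's test at adjusted p under 0.05. Of these, 9 rose and 11 fell (10 and 20 under quantile normalization), and they stood for 18 distinct sequences. UF_Msa_CF_124951 (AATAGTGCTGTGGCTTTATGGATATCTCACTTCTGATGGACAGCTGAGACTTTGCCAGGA) had a log2 level of −1.95 ± 0.61 (SD, n = 4) under EE2 and −6.24 ± 0.45 (SD, n = 4) in controls, relative to the 75th percentile of the array. It was well above background on 4 of 4 EE2 arrays and on 0 of 4 control arrays. With the main processing it was at least 5.41-fold higher under EE2 against the background limit, a bound not kept with normexp background correction and quantile normalization. The fitted log2 change, which is no bound as the control signal was not above background, was 4.29 (SE 0.35, adjusted p = 0.00257). It was 1.37 with normexp background correction and quantile normalization, where the offset by itself shrinks the change of a dim probe. That value therefore cannot decide on the bound. The probe did not pass with the replicate block or within the outer slide columns, with a range of adjusted p over the alternatives of 2.38e-05 to 0.134. UF_Msa_AF_107986 (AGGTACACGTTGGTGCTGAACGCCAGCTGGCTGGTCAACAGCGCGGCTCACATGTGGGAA) rose 15.9-fold, from −3.09 ± 0.92 (SD, n = 4) to 0.90 ± 1.12 (SD, n = 4), and was well above background on 2 of 4 control arrays. Its log2 change was 3.99 (SE 0.59, adjusted p = 0.0398), and 2.81 with normexp background correction. With normexp and quantile normalization it was 2.78 and did not pass (adjusted p = 0.0538, with a range over the alternatives of 0.000845 to 0.187).

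UF_Msa_CF_120215 (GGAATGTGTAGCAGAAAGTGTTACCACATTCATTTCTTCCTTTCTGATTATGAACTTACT) was 6.38-fold lower under EE2, at 3.36 ± 0.58 against 6.03 ± 0.75 (SD, n = 4 each). Its log2 change was −2.67 (SE 0.41, adjusted p = 0.0410), and it did not pass with median scaling or the deposited value table (adjusted p = 0.0564 for each) or with no filter on dim probes (adjusted p = 0.0717), with a range over the alternatives of 0.00177 to 0.249. UF_Msa_AD_200373 (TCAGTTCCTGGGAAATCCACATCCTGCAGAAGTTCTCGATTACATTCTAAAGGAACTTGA) was 5.33-fold lower, at −0.61 ± 0.60 against 1.81 ± 0.47 (SD, n = 4 each), with a log2 change of −2.42 (SE 0.35, adjusted p = 0.0389). It did not pass with no filter on dim probes (adjusted p = 0.0711, with a range over the alternatives of 0.000845 to 0.249). In each of these 4 probes, every EE2 array lay on one side of every control array, as the rule that named them required.

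**Figure D1:**
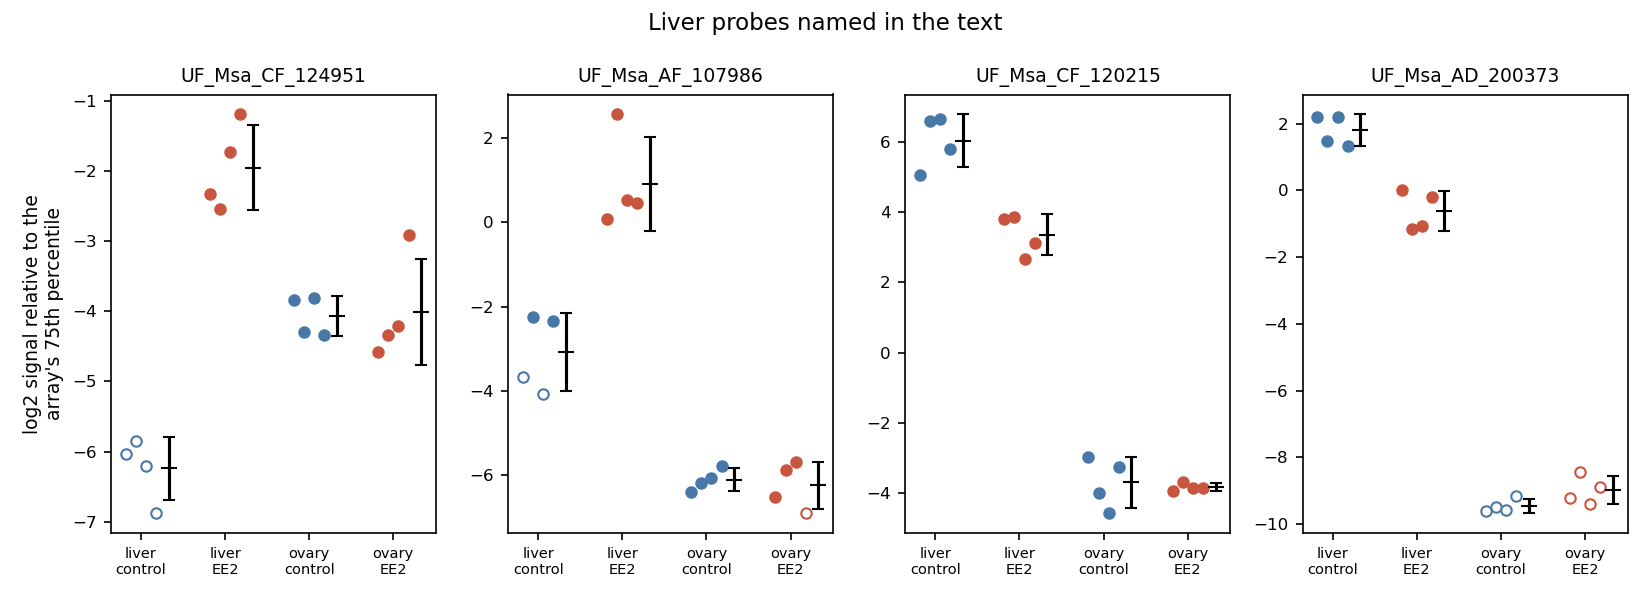
Log2 signal relative to the 75th percentile of the array (vertical axis) for the 4 liver probes named in the text, with 1 point per array, open where the spot was not well above background, and bars at the mean ± SD of 4 arrays. In liver, UF_Msa_CF_124951 averaged −1.95 under EE2 and −6.24 in controls.

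Among the 9 probes that rose, log2 changes ran from 1.82 to 3.99 apart from UF_Msa_CF_124951, which has only its bound of 5.41-fold, and 6 were at least 4-fold higher, 1 of them as a bound. Among the 11 that fell, log2 changes ran from −1.80 to −2.67, and 8 were at least 4-fold lower. Of the 10343 liver probes tested, 332 were well above background on 0 ovary arrays. These included 5 of the 11 that fell, which stood for 4 distinct sequences, and 0 of the 9 that rose. At unadjusted p under 0.05, 9.64% of them rose and 9.64% fell, against 9.39% and 7.74% of the rest. As a group these 332 probes had a mean log2 change of 0.04 ± 0.86 (SD across probes), against 0.04 for the rest (limma's camera, adjusted p = 0.643 over 4 groups tested). For them limma's fry gave adjusted p = 0.967 for a shift in 1 direction. Its test for changes in either direction gave an unadjusted p of 0.0104. The 100 brightest liver probes held 0 that passed limma's test and 3 at unadjusted p under 0.05, with a mean log2 change of 0.12 ± 0.30 (adjusted p = 0.413). Their shift relative to the rest was 0.08, and it passed unadjusted without EE2 replicate 2, at 0.17, and without control replicate 1, at 0.16, with the preset correlation. It was −0.04 without EE2 replicate 1, 0.03 without control replicate 2 and 0.0099 with quantile normalization. On all 8 arrays it had adjusted p = 0.896 with an estimated correlation. All 4 EE2 arrays lay above all 4 control arrays for 552 of 10286 probes and below for 376, together 9.02%, where chance gives 2.86% on average over splits. Probes can vary together across arrays, so a single split can lie far from that average. This share was not compared with that of other splits.

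At unadjusted p under 0.05, 1779 liver probes differed, where 517 are expected by chance and another split of the same 8 arrays gave 1638. Of the 1779, 54.6% were higher under EE2, against 48.7% with median scaling and 62.3% with normexp background correction, so which direction held the majority depended on the scaling. The count of 20 changed with any 1 array left out: it was 0 without EE2 replicate 1, 12 without EE2 replicate 2, 0 without EE2 replicate 3 and 0 without EE2 replicate 4. It was 10 without control replicate 1, 4 without control replicate 2, 1 without control replicate 3 and 41 without control replicate 4. With 1 array left out, UF_Msa_CF_124951 passed in each of the 4 cases that gave a value, those without a control array, with adjusted p of at most 0.0193. UF_Msa_AF_107986 passed only without EE2 replicate 2 or control replicate 4, UF_Msa_CF_120215 only without control replicate 1 or 4, and UF_Msa_AD_200373 only without control replicate 4. The highest adjusted p of these 3 probes was 0.140, 0.152 and 0.140, and their directions were kept. EE2 and control arrays lay in separate rows of the liver slide and each treatment had 1 tank, so row, tank and treatment cannot be told apart. Within the inner slide columns, 2 EE2 arrays against 2 controls gave 2398 probes, within the outer columns 0, and with outer or inner column as a block 1. For the 20 probes that passed, the outer change was a median of 0.838 times the inner change (0.531 to 1.49), a ratio that their selection on all 8 arrays favours near 1.

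**Figure D2:**
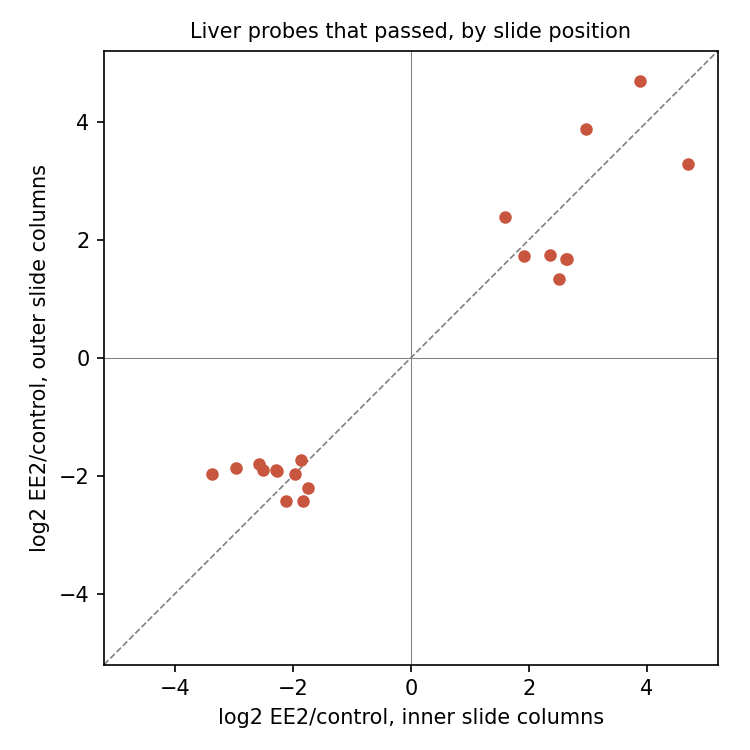
Log2 change under EE2 within the outer slide columns (vertical axis) against that within the inner slide columns (horizontal axis), with 1 point per liver probe that passed and the dashed line marking equal changes. The ratio of outer to inner change ran from 0.531 to 1.49 over the 20 probes, which were selected on both positions together.

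The ovary comparison addressed the same question in the gonad, and 0 of 12765 probes passed limma's test at adjusted p under 0.05, where the smallest adjusted p was 0.117. At unadjusted p under 0.05, 499 differed, where 638 are expected by chance, and no other tool was run. That number was 700 with normexp background correction, 715 with normexp and quantile normalization, 814 with array weights and 673 without ovary EE2 replicate 1, so its side of the chance value depended on the setting. The following probes are given as values that did not pass. UF_Msa_CF_126219 (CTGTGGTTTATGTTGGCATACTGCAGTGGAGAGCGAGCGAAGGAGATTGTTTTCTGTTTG) was at −5.57 ± 0.62 under EE2 and −8.41 ± 0.70 in controls (SD, n = 4 each), and was well above background on 4 of 4 EE2 arrays and 0 of 4 control arrays, a difference of at least 3.27-fold. Its fitted log2 difference, which is no bound, was 2.84 (SE 0.40, adjusted p = 0.202). With normexp background correction it was 1.02, where the 3.27-fold bound of the main processing was not kept. The offset by itself shrinks such a difference, so that value cannot decide on the bound. The adjusted p of this probe over the alternatives ran from 0.00518 to 0.820, passing under 4 of them. UF_Msa_CF_119780 (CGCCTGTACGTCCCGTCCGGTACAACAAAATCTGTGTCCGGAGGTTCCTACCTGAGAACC) was at −6.98 ± 0.46 under EE2 and −5.08 ± 0.70 in controls (SD, n = 4 each), a log2 difference of −1.90 (SE 0.36, adjusted p = 0.794). Non-overlapping EE2 and control arrays were seen for 371 of 12613 probes, or 2.94%, where chance gives 2.86% on average over splits.

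The 1582 ovary probes that were well above background on 0 liver arrays had a mean log2 difference of −0.08 ± 0.46, against −0.07 for the rest (limma's camera, adjusted p = 0.643). The 100 brightest ovary probes had a mean of −0.18 ± 0.10 against −0.07 for the rest (adjusted p = 0.000992), and adjusted p = 0.896 with an estimated correlation. Their shift relative to the rest was −0.12, and 0.01 without ovary EE2 replicate 4, −0.05 without ovary EE2 replicate 1, −0.0015 with quantile normalization and −0.0056 with normexp and quantile normalization, none of which passed. Ovary EE2 replicate 4 had a mean correlation of 0.949 with the other EE2 arrays, against 0.972 to 0.973 for those. The count of 0 became 2 without ovary control replicate 1, 2 without ovary control replicate 4 and 1 without ovary EE2 replicate 2, and it stayed 0 without ovary EE2 replicate 4. Within the inner slide columns 1 probe passed, within the outer columns 0, and with outer or inner column as a block 1. EE2 and control arrays lay in separate rows of the ovary slide too.

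The difference in EE2 effect between liver and ovary was tested as an interaction over 9740 probes, of which 7 passed, 4 with a higher effect in liver and 3 with a lower one (6 and 7 under median scaling). UF_Msa_CF_124951 had a higher effect in liver, with a fitted difference of 4.24 log2 units (SE 0.51, adjusted p = 0.00271) and an ovary change of 0.06 (SE 0.35, adjusted p = 0.982). This difference is no bound, as the liver controls were not above background and the liver rise is given only as a bound of 5.41-fold under the main processing. It was 1.53 with normexp background correction, which did not pass (adjusted p = 0.124, with a range over the alternatives of 1e-13 to 0.124). There too the offset by itself shrinks the change of a dim probe. UF_Msa_AF_107986 had an effect 4.12 log2 units higher (SE 0.70, adjusted p = 0.0349), its ovary change being −0.13 (SE 0.28, adjusted p = 0.943). The value for UF_Msa_CF_120215 was −2.54 (SE 0.55, adjusted p = 0.0702), which did not pass, with an ovary change of −0.13 (SE 0.32, adjusted p = 0.948). At unadjusted p under 0.05, 1283 probes differed, where 487 are expected by chance.

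The interaction count was 52, 34, 4 and 45 without liver control replicates 1, 2, 3 and 4. It was 14, 2 and 1 without liver EE2 replicates 2, 3 and 4. It was 2 and 22 without ovary EE2 replicates 1 and 4, and 3 and 2 without ovary control replicates 1 and 3. UF_Msa_AF_107986 no longer passed without liver EE2 replicate 3 or 4, liver control replicate 3, ovary EE2 replicate 1 or 2, or any 1 ovary control replicate, its adjusted p reaching 0.0875. UF_Msa_CF_120215 passed without liver control replicate 1 (adjusted p = 0.0252, with a range over the alternatives of 0.000526 to 0.181). Each tissue was on its own slide, so slide and tissue cannot be told apart, and with outer or inner column as a block 25 probes passed.

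The overlap of both tissues was 0 probes, as limma called 0 in ovary. At unadjusted p under 0.05 in both, 10 probes were higher under EE2 in both tissues, out of 913 in liver and 115 in ovary, where 10.8 are expected (odds ratio 0.920, Fisher's exact p = 1, two-sided). Likewise 16 were lower in both, out of 747 and 183, where 14.035 are expected (odds ratio 1.16, Fisher's exact p = 0.574). Across the 9740 probes, which are not independent replicates, the log2 changes in liver and ovary had a Pearson r of 0.058 and a Spearman rho of 0.079. The 15 of the 20 liver probes measured in ovary had ovary changes with a median of −0.02 (−0.20 to 0.30) in the direction of their liver change, whose median size was 2.12.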

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

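The splits of the samples, the tests of GC content and signal level and of noisier outer arrays were set before their results were seen, and the tests of slide row, tank, noisy spots, liver RNA and a common column effect, and a second draw of splits for the interaction, were chosen only after the results were seen.

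The liver count of 20 was larger than that of any other split: 1 of the 35 splits of the 8 arrays, the real one, gave as many, and the highest of the others was 1. As 1 of 35 is the smallest share that 35 splits can give, chance is made less likely but is not excluded. At unadjusted p under 0.05 the gap between splits was smaller, with 1779 probes in the real split against 1638 in the highest of the others. A row effect alike on both slides would move the 15 probes measured in ovary the other way there, since EE2 arrays lay in opposite rows of the slides, and their median ovary log2 change was −0.0164 in the direction of the liver change. A row effect of the liver slide alone, or the tank, cannot be told apart from EE2, as 0 EE2 arrays lay in the row of the controls. The response to EE2 stays open beside these.

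Ovary EE2 replicate 4 stood apart from its group: its mean correlation with the other EE2 arrays was 0.949, against 0.972 to 0.973, and its spike-in mean was −0.59, against 1.03 to 1.05 (0.75 to 2.15 on ovary control arrays). These were 2 of 38 groups of 4 tested for a sample far from the others, where chance picks about 1 in 20. Such a test cannot flag a group that is split into 2 and 2. Noisy spots are argued against by a median difference between probes of 1 sequence of 0.0948 there (highest of the other ovary arrays 0.121), and liver RNA by 2% of the 50 brightest such liver probes being well above background there. GC content and signal level explained 2.32% of its deviation, leaving an SD of 0.88 against at most 0.47 for the whole deviation of each other ovary array. A difference between the fish or a mislabelled sample was not tested, nor was the cause of its spike-in mean. The ovary count was 0 with and without this array.

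The EE2 difference in liver was seen in 2398 probes within the inner slide columns and in 0 within the outer ones, where 1036 had an unadjusted p under 0.05 by limma, and the log2 changes of both correlated at 0.132 across probes. Of the 36 choices of 2 EE2 and 2 control arrays, the inner columns gave the highest count, and the second highest was 447. The liver EE2 arrays were themselves divided by column. Inner and outer EE2 arrays correlated at 0.950 to 0.957, against 0.978 between the 2 inner and 0.989 between the 2 outer ones. Outer EE2 arrays correlated at 0.970 to 0.973 with outer controls, and inner with outer controls at 0.954 to 0.971. The inner minus outer differences in EE2 and control correlated at −0.137, which was not needed to decide on a column effect common to both groups. An effect alike in both on the log2 scale cancels from the EE2 minus control change, so it could not by itself give this pattern. Over the 2398 probes the median ratio of outer to inner change was 0.0159. Their selection on the inner arrays favours a ratio near 0, so it cannot decide whether noisier outer arrays hid the same change. Over all probes tested the median SE was 0.294 within the outer columns and 0.283 within the inner ones, which argues against much noisier outer arrays. Differences between the fish, and a column effect in 1 treatment row alone, were not tested, and no biological explanation was tested.

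The EE2 effect differed between liver and ovary for 7 probes by the interaction test, with fitted differences of 4.24 log2 units for UF_Msa_CF_124951 and 4.12 for UF_Msa_AF_107986. The first is no bound, as its liver controls were not above background, and it was 1.53 with normexp background correction, which did not pass. The offset of that correction by itself shrinks the change of a dim probe. In a draw of 100 splits within both tissues, 7 gave as many as the real count of 7, and the highest other gave 14, so chance is not excluded. A second draw with the arrays in another order gave 3 of 100 (highest other 12), and both draws together gave 9 of 184, or 4.89%, so the share lies on either side of 5% depending on the draw. For the ovary count of 0 by limma, all 35 splits necessarily gave as many, and the highest other was 4. At unadjusted p under 0.05, 15 of the 35 splits gave as many as the real 499 probes, so chance is not excluded. That highest split set outer against inner columns, and the ovary count with column as a block was 1.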

How the results depend on the processing

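The fits within slide columns, those with column as a block and all settings of the 4 probe groups were chosen only after the data were seen, while the other alternatives were planned. The cause was not tested for any of the changes below, except where fewer arrays, a different number of probes tested or a looser threshold is the alternative itself. The liver count of 20 became 50 with normexp background correction, 52 with that and quantile normalization, 2 with no filter on dim probes, 32 with probes well above background on every array, 529 with all 16 arrays in 1 fit, 1 with slide column as a block, 0 within the outer columns, 2398 within the inner columns, 70 at adjusted p under 0.1 and 1779 at unadjusted p under 0.05. With the replicate block, which is also a block on each slide column, it was 0 by limma, with 1400 at unadjusted p under 0.05. After group means were removed, 0 of 4 liver EE2 arrays correlated most with the control array of their own number. It ran from 0 to 41 with 1 array left out. The ovary count of 0 became 2 with quantile normalization, 1 with no filter, 2 with array weights, 1 with the replicate block, 1 with slide column as a block, 1 with all 16 arrays in 1 fit, 1 within the inner columns and 499 at unadjusted p under 0.05, and ran from 0 to 2 with 1 array left out.

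The interaction count of 7 became 13 with median scaling, 19 with normexp, 46 with normexp and quantile normalization, 32 with no filter, 14 with trend and robust, 95 with array weights, 13 with the deposited value table, 0 with the replicate block (1094 at unadjusted p under 0.05, limma), 25 with slide column as a block, 327 with separate tissue fits and a z test, 65 at adjusted p under 0.1 and 1283 at unadjusted p under 0.05. It ran from 1 to 52 with 1 array left out. The overlap of 0 became 26 at unadjusted p under 0.05 in both tissues, and was 0 with quantile normalization and with no filter. The shift of the 100 brightest ovary probes ran from −0.229 to 0.0098 with 1 array left out, reversed without ovary EE2 replicate 4, and was −0.0015 with quantile normalization and −0.0056 with normexp and quantile normalization, which did not pass, and the cause was not tested. The 4 named liver probes kept their direction in 82 of 82 alternative values, and in 36 they no longer passed. All 20 liver probes were shared with the calls under quantile normalization. Among ovary probes at unadjusted p under 0.05, 36.9% were higher under EE2, against 57.3% with median scaling and 52.3% with quantile normalization, so their direction depends on the scaling. The gene list alternatives and the slide as a block were not run, the first for want of gene names and the second because each slide held 1 tissue. UF_Msa_CF_124951 has no value where a liver EE2 array is left out, as it was then well above background on too few arrays. Signal over background limits which probes could be tested, and folds against groups that were not above background are bounds under the main processing only.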

Other observations

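The tests of both orientations and the spike-in values with 1 array left out were chosen only after the results were seen. Entries printed in both orientations gave 197 pairs of probes, of which 118 had both probes detected in liver, 47 had 1 and 32 had neither, with 84, 80 and 33 in ovary. UF_Msa_AD_200373 is 1 of such a pair, and its partner (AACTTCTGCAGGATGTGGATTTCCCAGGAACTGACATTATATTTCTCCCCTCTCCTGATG, chosen after its values were seen), complementary to it over 34 nt, also fell in liver, with a log2 change of −2.09 (SE 0.30, adjusted p = 0.0389). Its level was 2.03 ± 0.20 under EE2 and 4.12 ± 0.56 in controls (SD, n = 4 each), with 4 of 4 EE2 arrays below the controls. In the pair of UF_Msa_AD_200106 and UF_Msa_AD_200227, complementary over 51 nt and both detected in liver, only UF_Msa_AD_200227 passed. By limma its log2 change was −2.19 (adjusted p = 0.0389), and that of UF_Msa_AD_200106 was −0.34 (adjusted p = 0.530). Across the 118 liver pairs, which are not independent replicates, the log2 changes had a Pearson r of 0.274 and a Spearman rho of 0.141 (permutation p = 0.00332 for r, adjusted p = 0.00664 over 2 tissues), and r was 0.211 without the 2 farthest pairs. Of these pairs, 31 shared at least 15 complementary nt, with r 0.440 and rho 0.053 (permutation p = 0.0196, adjusted p = 0.0982 over 5 relations), and r was 0.040 without the 2 farthest pairs. Over the 30 such pairs without the called pair r was 0.160 (permutation p = 0.397, adjusted p = 0.661), so the relation in complementary pairs rested on the called pair, and over the 87 other pairs r was 0.197 (permutation p = 0.0677, adjusted p = 0.169). In ovary r was −0.01 (permutation p = 0.943, adjusted p = 0.943). A hypothesis is that transcripts of both strands may change together in liver: without the called pair r was 0.183 (permutation p = 0.0491, adjusted p = 0.0981), which did not pass, so this stays open.

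Probes well above background on 4 of 4 arrays of 1 group and 0 of 4 of the other numbered 7 for EE2 and 2 for control in liver, and 4 and 15 in ovary. As many or more were found in 11 of 35 liver splits and in 4 of 35 ovary splits, the real ones included. The highest other counts were 239 in liver and 83 in ovary. Probe pairs of 1 sequence had log2 changes that correlated at 0.983 over 45 pairs in liver and 0.875 over 37 pairs in ovary. The spike-in mean differed between EE2 and control by 0.10 in liver (exact permutation p = 0.657, two-sided) and by −0.74 in ovary (exact permutation p = 0.286, two-sided). In liver it was 0.22 without EE2 replicate 3, −0.02 without EE2 replicate 4, 0.05 without control replicate 2, 0.06 without control replicate 3 and 0.16 without control replicate 4. In ovary it was −0.33 without EE2 replicate 4 and −0.48 without control replicate 3.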
